A study of Mus musculus with 19 samples.

How the data were processed

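RNA was measured by sequencing in the cerebral cortex of C57BL/6 mice of the line called Setdb1-CK-cKO in the labels, in which the gene of the histone H3 lysine 9 methyltransferase SETDB1 was targeted, and of wildtype (WT) mice. The line carries the label KO here. Astrocytes were isolated from dissociated adult brain with magnetic beads against the surface antigen ACSA-2, and each of the 4 libraries (2 per genotype) pooled 2 animals, aged 3 and 6 months. Neuronal nuclei were sorted by flow cytometry for the nuclear protein NeuN at 5 months, with 1 animal per library and 3 libraries per genotype, so these libraries hold nuclear RNA. Cortex tissue was taken from 3 animals each of WT, KO and DKO, the label for mice that carry the Setdb1 knockout together with a knockout of P2rx7, the gene of an ATP-gated ion channel. The cortex animals were 6 to 8 months old and were sequenced in 2 batches. Replicates 1 and 2 of every genotype formed batch 1 (8 months, except 7 months for DKO replicate 1) and replicate 3 formed batch 2 (WT 7 months, KO and DKO 6 months).

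The deposited values are raw read counts per feature that the authors made with featureCounts. The version was 2.0.1 for astrocytes, 2.0.3 for neuronal nuclei and 1.6.0 for cortex tissue, per the file headers, while the submitters' processing notes name version 1.6.3. The same notes name FastQC, Trim Galore, HISAT2, SAMtools 1.9 and DESeq2 and the genome build mm10. The parameters of trimming and alignment are not given in the sources used here. Per the file headers, no option for strand was set, so a gene cannot be told apart from an antisense partner. Whether options for multimapping reads or for reads over several features were set was not established here. If they were not set, such reads were not counted, and near-identical copies, such as members of gene families, lost the reads they share. The counts of such copies are uncertain in either case. The nuclei files give the paired-end option without the option for counting pairs, which counts each read of a pair in that version. Per the file headers, the astrocyte and nuclei counts used 1 annotation that joins the exons of genes with single repeat copies. A read over an exon and a repeat was dropped, unless reads over several features were counted. The cortex counts used the genes of GENCODE vM20 alone, and repeats in cortex tissue were not analysed here.

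All files share 54752 gene identifiers. Symbols came from the reference annotation, which matched 53861 identifiers by version and 54723 in all. Positions were those deposited with the counts. The astrocyte and nuclei files also hold 5147736 repeat copies of 1554 names (subfamilies in what follows), of which 45.13% lie within the span of a gene and 2.85% overlap an exon. Gene counts summed to 15002934 to 16400876 per astrocyte library, 17163131 to 22110110 per nuclei library and 16921839 to 19428285 per cortex library. Repeat copies took 2.13 to 2.43% of the assigned counts in astrocytes and 44.9 to 54.81% in nuclei, where 90.77 to 92.03% of the repeat counts lay within gene spans. Replicates of a group differed by more than sampling noise in each group (chi-square per degree of freedom 7.03 to 44.67), so none was treated as a copy of another.

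CPM values, which scale each count to the total of its library, were computed from the deposited counts with TMM factors. Each comparison was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after the default filterByExpr filter, with Benjamini-Hochberg adjustment and a threshold of 0.05. The adjusted p-values in the text come from this test unless another is named. Astrocytes and nuclei were fitted apart, with genotype as the term. The 9 cortex libraries were fitted together with genotype and batch. Whether the KO effect differs between nuclei and astrocytes was tested as an interaction in 1 fit of those 10 libraries, in which the kind of material also stands for sequencing platform, age, sex and nuclear against cellular RNA. Repeat copies were summed to subfamilies, which were fitted in the same model as the genes and adjusted over the subfamilies. Copies were also tested singly, with library sizes and factors from the genes.

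Before the data were examined, 36 gene lists (pathways, gene families and markers of the cell types that the samples could hold) were fixed. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 where at least 5 members were tested, and called at an adjusted p under 0.05 over the lists. Each called list is given with its adjusted p when the correlation is estimated from the data. For a list the text also gives how many members pass when the adjustment is made over the list alone. The genes named were chosen by a rule fixed at the same time. It takes Setdb1 and P2rx7, and the 8 highest and 8 lowest log2 fold changes among genes past the threshold whose groups do not overlap in CPM and whose higher group has a mean CPM of at least 1. Names that are only identifiers, pseudogenes, Xist, Tsix and Y-linked genes were left out. The rule adds the 3 members with the smallest p of each list that was called or had 3 members past the threshold. Genes named for cortex KO are given again for DKO. A few features outside the rule are marked as chosen after their values were seen. Some genes that the rule takes are not reported here.

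Where all libraries of a group were at 0, the fold is given as at least a value computed against a floor of 3 counts over the group. With 1 to 3 counts the ratio of the groups is given with its 95% interval. Both cover counting error only. In nuclei each read of a pair was counted, so 1 fragment can give 2 counts. There the intervals can be too narrow and the bounds too high. The p-values measure the spread between libraries, which for astrocytes is the spread between pools of 2 animals. The targeted exons are not given in the sources used here, and the counts cover whole genes.

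The fits were tested on simulated data drawn from the means and library sizes of the real libraries. All features were given a common spread, no batch or other sample structure was drawn, and genes with the lowest CPM were not among those changed. For nuclei only a random part of the copies was drawn (37601 tested). Real recovery may therefore be lower, and wrong calls more frequent, than the values here. At a 2-fold change they recovered 89.6% of the changed genes in nuclei, 32.8% in astrocytes, 94% in cortex KO, 94% in DKO against KO and 92.5% in DKO against WT. At 4-fold these shares were 100% in nuclei, 98.5% in astrocytes and 100% in each of the cortex comparisons, and at 1.5-fold they were 37.3%, 4.5%, 32.8%, 34.3% and 40.3% in the same order. Over the tested genes the numbers of unchanged genes called were 6, 3, 11, 11 and 7. The interaction recovered 77.5% at 4-fold, and the test of subfamilies recovered 93.3% in nuclei and 46.7% in astrocytes at 2-fold. Single copies changed 4-fold were recovered at 100% in nuclei and 97.5% in astrocytes.

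The alternatives tried were RLE factors, no filter, a filter at a CPM of 1, DESeq2 1.42.0, an added log2 limit of 1, each library left out in turn and the replicate number as a block. For the cortex they also included no batch term, batch 1 alone and only the 6 libraries compared. For lists they were camera with estimated correlation, camera on ranks and fry. For repeats they were other library factors, a filter at 20 counts and copies outside genes alone. Other calculations and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.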

Results

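The series asks how the histone methyltransferase SETDB1 affects gene and repeat expression in the mouse cortex, and how a knockout of P2rx7 alters its effect in cortex tissue. RNA sequencing counts were compared between KO and WT in isolated astrocytes (2 libraries per genotype), in sorted neuronal nuclei (3 per genotype) and in cortex tissue (3 per genotype). A DKO group of 3 libraries was also measured in cortex. Gene counts per library were 15002934 to 16400876 in astrocytes, 17163131 to 22110110 in nuclei and 16921839 to 19428285 in cortex. The 10 most abundant genes took 10.65 to 14.13% of the counts in astrocytes, 6.09 to 7.39% in nuclei and 4.56 to 6.1% in cortex. Mitochondrially encoded genes took 5.855 to 9.311% in astrocytes, 0.01 to 0.027% in nuclei and 4.01 to 5.504% in cortex. Transcripts of Xist, which is expressed from the inactive X chromosome of females, were at 327.5 to 603.2 CPM in the astrocyte libraries and at 527.5 to 568.5 CPM in cortex batch 2. They were at most at 1.92 CPM in nuclei and 0.158 CPM in cortex batch 1. Batch and sex therefore cannot be told apart in cortex.

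The targeted genes were measured in every group first. Setdb1 (ENSMUSG00000015697.14, mm10 chromosome 3, 95323525 to 95357202) was at 30.6 ± 3.42 CPM in WT cortex and at 15.6 ± 3.10 CPM in cortex labelled KO (SD, n = 3 each). It fell by 0.97 on the log2 scale (SE 0.145, edgeR quasi-likelihood test, adjusted p = 0.0107), and every KO library lay below every WT library. Within batch 1 the log2 change was −0.95 (adjusted p = 0.0165). Batch 2 holds 1 library per genotype and gives no test. The call was lost without WT replicate 1, WT replicate 2 or KO replicate 1, with adjusted p up to 0.0743 and log2 changes of −1.13 to −0.87. In the cortex labelled DKO Setdb1 was at 16.5 ± 1.33 CPM (SD, n = 3). The log2 change was −0.89 against WT (adjusted p = 0.0222) and 0.08 against KO (adjusted p = 1). Within batch 1 it was −1.05 against WT (adjusted p = 0.0226). The call against WT was kept only without DKO replicate 3, and the adjusted p reached 0.136 for the other libraries left out. In the astrocyte fraction Setdb1 was at 34.5 ± 0.976 CPM in WT and 24.6 ± 1.54 CPM in KO (SD, n = 2 each), and the log2 change of −0.49 (SE 0.172) did not pass the test (adjusted p = 0.492). In neuronal nuclei it was at 133.9 ± 2.70 CPM in WT and 127.1 ± 9.02 CPM in the libraries labelled KO (SD, n = 3 each, log2 change −0.08, adjusted p = 0.895). The counts cover the whole gene and the targeted exons are not given in the sources used here. This level therefore does not check the genotype of the nuclei. Directions drawn there use the labels, which are weighed below with the genes called higher in cortex KO.

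P2rx7 (ENSMUSG00000029468.17, chromosome 5, 122643911 to 122691432), whose product is an ATP-gated channel of microglia and other cells, was not lower in the cortex labelled DKO. It was at 8.97 ± 0.943 CPM in WT, 19.6 ± 6.45 CPM in KO and 22.3 ± 6.96 CPM in DKO (SD, n = 3 each). The DKO libraries held 16.3, 29.95 and 20.78 CPM. The log2 change was 0.22 in DKO against KO (adjusted p = 1), 1.32 in DKO against WT (adjusted p = 0.058) and 1.10 in KO against WT (SE 0.263, adjusted p = 0.0895). Within batch 1 the values against WT were 1.38 for DKO (adjusted p = 0.0976) and 0.86 for KO (adjusted p = 0.145). Counts over the whole gene cannot show the loss of part of it, so this level does not check the label DKO. In neuronal nuclei P2rx7 rose in the libraries labelled KO, to 82.7 ± 10.4 CPM from 5.59 ± 0.341 CPM in WT (SD, n = 3 each, log2 change 3.89, SE 0.143, adjusted p = 1.49e-09). In the astrocyte fraction it was at 22.7 ± 3.01 CPM in WT and 20.3 ± 2.38 CPM in KO (SD, n = 2 each, adjusted p = 0.945).

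**Figure D1:**
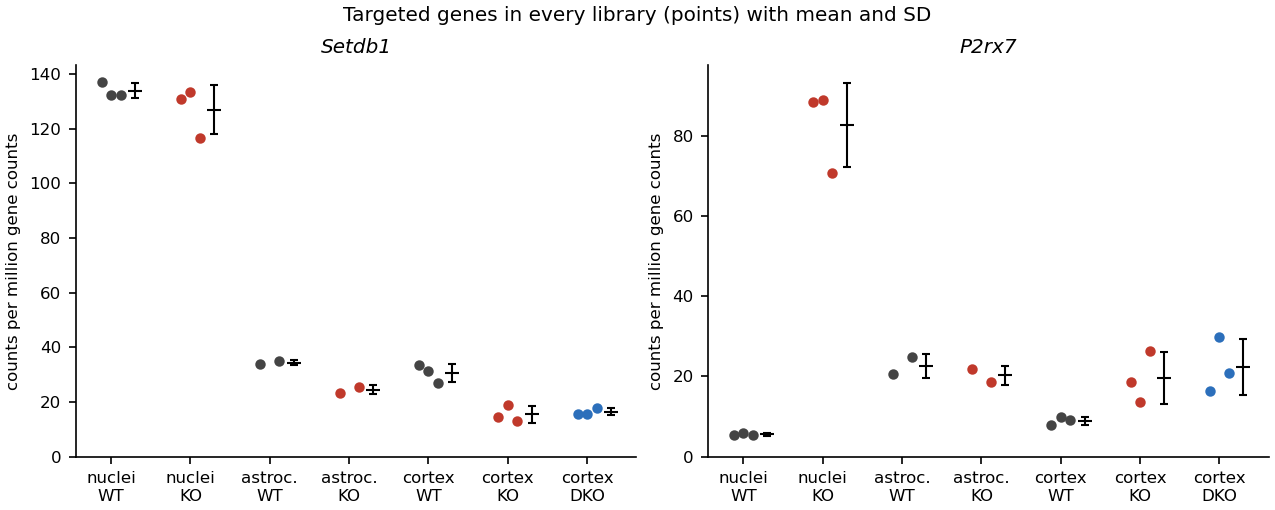
CPM of Setdb1 and P2rx7 in each library (points) of the 7 groups, with the mean and SD of each group. Setdb1 is lower in both mutant cortex groups than in WT, and P2rx7 is high in the nuclei labelled KO and not lower in the cortex labelled DKO.

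In the neuronal nuclei labelled KO, genes of the clustered protocadherins, cell-surface adhesion proteins of neurons, and some germline genes rose. Of 54 tested clustered protocadherins, 41 rose and 0 fell (48 and 0 adjusted over the list alone), and all 54 had a positive log2 change, with a median of 0.96. Pcdha1 (chromosome 18, 36930184 to 37187661) rose from 6.49 ± 1.15 to 50.2 ± 2.97 CPM (SD, n = 3 each, log2 change 2.95, SE 0.153, adjusted p = 2.99e-08). Pcdhga8 rose from 28.3 ± 2.89 to 101 ± 4.73 CPM (log2 change 1.84, adjusted p = 1.21e-07) and Pcdhga7 by 1.65 on the log2 scale (adjusted p = 1.52e-06). Members of the alpha and gamma clusters share 3' exons, and how reads over nested members were assigned was not established. Values of single members are therefore uncertain. Of 21 tested germline genes, 8 rose and 0 fell (13 and 0 adjusted over the list alone, median log2 change 0.96). Stag3, a cohesin subunit of meiosis, rose from 3.57 to 52.1 ± 5.07 CPM (SD, n = 3, log2 change 3.87, adjusted p = 1.27e-08). Mael and Piwil1, which act in the piRNA pathway that silences transposons, rose by 3.81 (adjusted p = 0.00127) and 2.39 (adjusted p = 0.000843).

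Across all genes tested in nuclei, 285 rose and 60 fell of 21975, and 2056 had an unadjusted p under 0.05. Of the higher genes, 243 are outside the protocadherin clusters. The change was at least 2-fold in 203 of the higher and 22 of the lower genes. The highest was Tnxa (chromosome 17, 34771395 to 34801623), with 0.0331 CPM in WT and 14.9 CPM in KO (ratio of the groups 409, 95% interval 113 to 3390, adjusted p = 4.57e-08). Mnd1, a meiotic recombination gene, had a log2 change of 6.63 (SE 0.431, 7.74 CPM in KO, adjusted p = 2.3e-07), and Zfp981 had a ratio of 99.1 (17.4 to 3950, adjusted p = 0.000208). Some genes had no count in WT nuclei. They were the kallikrein gene Klk1b24 (at least 37.7-fold higher, adjusted p = 0.000144), the olfactory receptor genes Olfr1505 (at least 36.5-fold) and Olfr1504 (at least 22.3-fold), and Prr23a2 (at least 20.8-fold) and Prr23a3 (at least 19.5-fold). These belong to families with near-identical copies, so their counts are uncertain. As each read of a pair was counted in nuclei, the intervals above can be too narrow and the bounds too high.

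The lower genes of nuclei included Rab37, a small GTPase gene, which fell by 1.76 on the log2 scale (4.61 CPM in WT, 1.37 CPM in KO, SE 0.292, adjusted p = 0.00359). Cracr2a fell by 1.24 (14.5 CPM in WT, 6.12 CPM in KO, adjusted p = 0.00362). Both passed in all 6 fits that left out 1 library. Casp1, the gene of the protease that matures interleukin-1 beta, fell by 2.37 (1.40 ± 0.345 CPM in WT, 0.26 ± 0.173 CPM in KO, SD, n = 3 each, adjusted p = 0.0337), as did Tnfaip2 (adjusted p = 0.0337). Armc4 fell by 2.46 (adjusted p = 0.0485), Lgr6 by 2.28 (adjusted p = 0.0185), Stat4 by 2.17 (adjusted p = 0.0488) and BC006965 by 1.28 (adjusted p = 0.0423). These 6 calls depended on single libraries. Casp1 passed only without KO replicate 3, with adjusted p up to 0.198. Armc4, Tnfaip2, Stat4 and BC006965 passed only without WT replicate 3, with adjusted p up to 0.211, 0.221, 0.262 and 0.157. Lgr6 was lost without WT replicate 2, WT replicate 3, KO replicate 1 or KO replicate 2 (up to 0.117). Without KO replicate 1 the count of changed genes was 220, of which 26 were lower. Lower genes numbered 129 without WT replicate 3, 33 without WT replicate 1, 23 without KO replicate 2 and 37 without KO replicate 3.

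Camera called 6 of the 35 lists that could be tested in nuclei, 5 higher and 1 lower. The protocadherins (adjusted p = 2.48e-145) and the germline genes (adjusted p = 6.42e-21) were also called with an estimated correlation (adjusted p = 0.0195 and 0.0156). Genes of the integrated stress response and unfolded protein response were called higher, with a median log2 change of 0.41 (adjusted p = 6.58e-09, and adjusted p = 0.372 with an estimated correlation). Of 20 members, 2 rose and 0 fell (9 and 0 adjusted over the list alone). Trib3, a pseudokinase gene induced by endoplasmic reticulum stress, had a log2 change of 2.12 (adjusted p = 0.0277). Herpud1, which acts in endoplasmic reticulum-associated degradation, had 0.51 (adjusted p = 0.0393), and Slc7a11 had 0.84 (adjusted p = 0.117). Trib3 was lost without WT replicate 2, KO replicate 1 or KO replicate 2 (up to 0.142), and Herpud1 was kept only without WT replicate 3 (otherwise up to 0.231).

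The purinergic receptors and ectonucleotidases were called higher (adjusted p = 0.00278, and adjusted p = 0.197 with an estimated correlation), with a median of 0.03 against a mean of 0.21. Of 21 members, 2 rose and 0 fell (3 and 0 adjusted over the list alone). These were P2rx7 and Adk, the adenosine kinase gene (log2 change 0.68, adjusted p = 0.0169), while P2rx6 had 0.44 (adjusted p = 0.173). Adk was lost without WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 2 (up to 0.113). The p53 targets and cell cycle inhibitors were called higher, with a median of 0.23 (adjusted p = 0.0459, and adjusted p = 0.877 with an estimated correlation). Of 14 members 1 rose, also adjusted over the list alone, namely Cdkn2b, a cyclin-dependent kinase inhibitor gene (log2 change 2.63, adjusted p = 0.0292), and Sesn1 had 0.30 (adjusted p = 0.314). Cdkn2b was lost without the same 4 libraries as Adk (up to 0.198), and the list without KO replicate 3 (0.209). The cholesterol synthesis genes were called lower with 0 of 22 past the threshold, also adjusted over the list alone (median −0.13, adjusted p = 0.0143, and adjusted p = 0.877 with an estimated correlation). This call was lost without WT replicate 3 or KO replicate 2 (up to 0.175). Hsd17b7 had −0.50 (adjusted p = 0.142).

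The other 29 lists had adjusted p of 0.0709 to 0.925 in nuclei. Among them were the interferon-stimulated genes (median −0.10, 0 of 32 past the threshold, adjusted p = 0.568) and the markers of excitatory neurons (adjusted p = 0.677), inhibitory neurons (adjusted p = 0.705), astrocytes (adjusted p = 0.0758) and oligodendrocytes (adjusted p = 0.67). For the inflammasome and P2X7 pathway the median was −0.08, while its mean of 0.06 and the test pointed up (adjusted p = 0.0709).

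**Figure D2:**
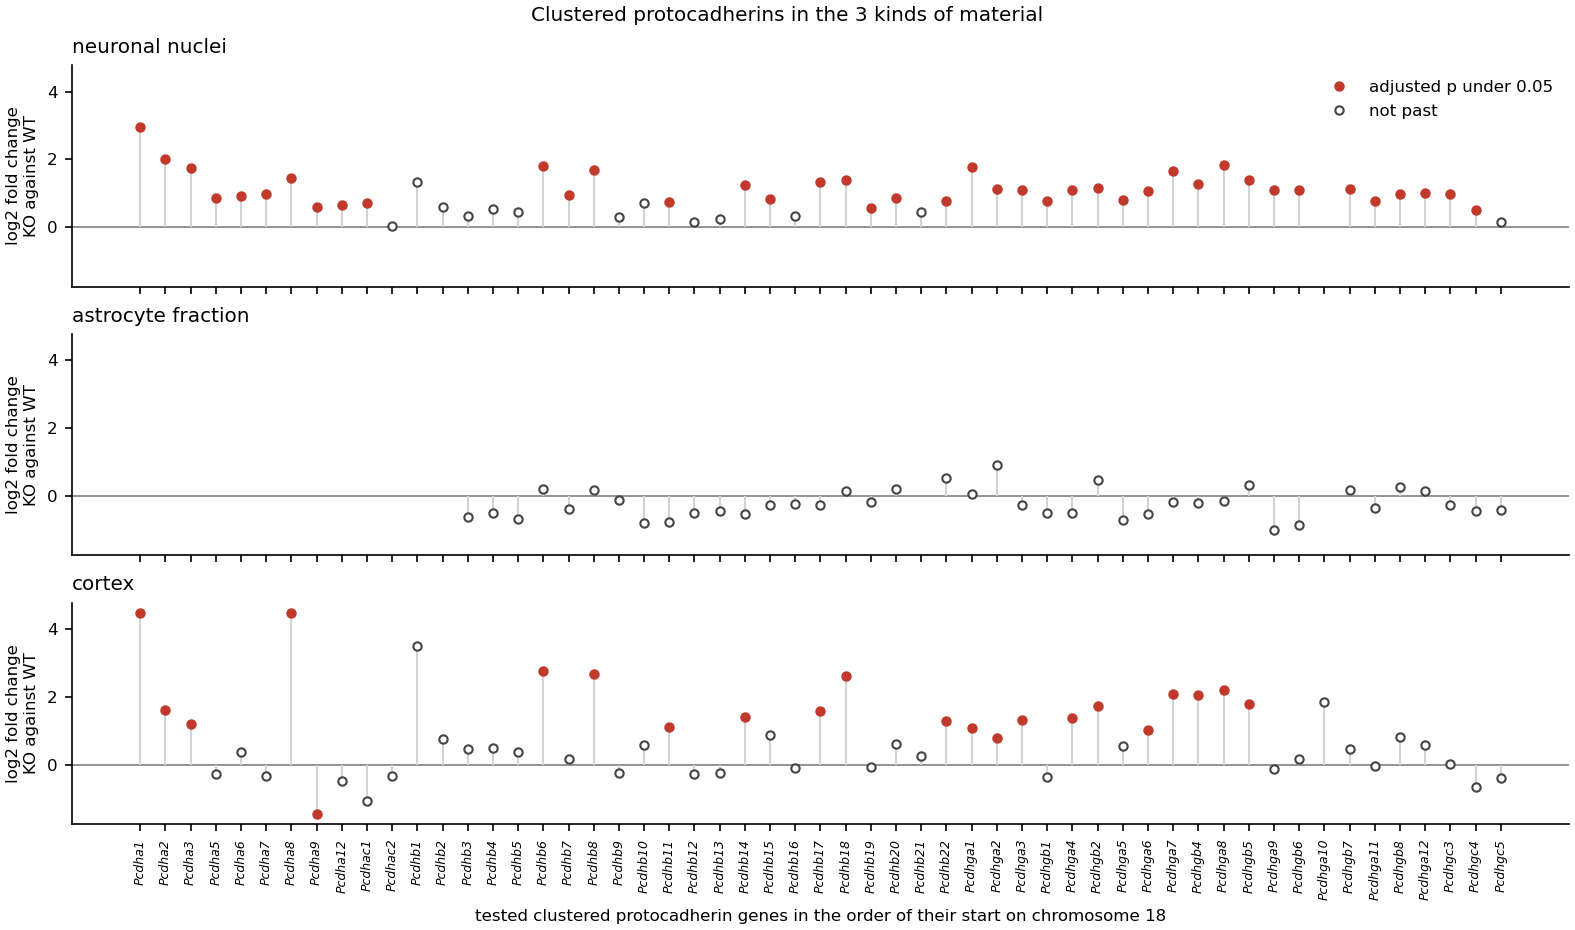
Log2 fold change of KO against WT for each tested clustered protocadherin gene in its order on chromosome 18, in nuclei, the astrocyte fraction and cortex tissue, with filled points for an adjusted p under 0.05. All 54 members are above 0 in nuclei, while 39 are above and 16 below 0 in cortex, where Pcdha9 fell.

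Of 1470 repeat subfamilies tested in the nuclei labelled KO, 5 rose and 0 fell. The 5 are internal parts of retroviruses with long terminal repeats. MMTV-int rose by 2.25 on the log2 scale (SE 0.164, from 10.2 to 48.3 ± 10.3 CPM, SD, n = 3, adjusted p = 1.13e-06) and MuLV-int by 2.02 (to 93.6 CPM, adjusted p = 1.13e-06). MMERVK10C-int rose by 1.37 (from 312 to 806 CPM, adjusted p = 2.87e-06) and IAP-d-int by 1.17 (from 62.6 to 141 CPM, adjusted p = 2.44e-05). IAPEz-int rose by 0.79 (from 2558 to 4410 CPM, adjusted p = 0.00619) and was lost without WT replicate 2 (0.104). With only copies that overlap no gene, MMTV-int had 2.02 (adjusted p = 0.0637) and MuLV-int 0.74 (adjusted p = 0.274), so both calls were lost, and the other 3 were kept. A copy within Coro2a (chromosome 4, 46576472 to 46583716), singled out after its values were seen, held 93.45% of the KO counts of MMTV-int. It had 5332 counts over the KO libraries and 899 in WT (log2 change 2.50, adjusted p = 3.05e-15).

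Among 469065 single copies tested in nuclei, 2842 rose and 490 fell. The number that fell depended on single libraries. It was 1355 without WT replicate 3, 187 without WT replicate 1, 278 without WT replicate 2 and 274 without KO replicate 3, while 2425 to 3004 rose in the fits without 1 library. Outside genes, where reads of introns do not add to a repeat, 2026 of 35548 rose and 42 fell, and such copies tested alone gave 2254 higher and 155 lower. Over all tested copies of a subfamily, within and outside genes, 156 of 311 of MMERVK10C-int rose (50.16%) and 411 of 2291 of IAPEz-int. These subfamilies hold 3230 and 7319 copies, and a copy silent in WT is tested only if its KO counts are high enough. The shares therefore do not stand for the whole subfamilies. Among the copies without a count in WT nuclei were an RLTR10D (chromosome 17, 34781326 to 34781701), an RLTR10B2 (34786637 to 34787135) and an RMER15-int (34785601 to 34786308) within Tnxa. Another was an IAPEY3-int copy outside genes on chromosome 10 (40563596 to 40565243), 673 bp from the gene Gm17795. The lowest were an Lx8 copy within Fat1 (chromosome 8, 44965162 to 44965725, log2 change −3.91) and a MuLV-int copy within Vstm2a (chromosome 11, 16402629 to 16403662, log2 change −3.58). Both lost the call without WT replicate 1 (adjusted p = 0.0569 and 0.215).

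In the astrocyte fraction labelled KO a small set of genes rose and Cntn2 fell. Tcfl5, a transcription factor gene of spermatogenesis, rose from 0.244 to 26.9 CPM (log2 change 6.74, SE 0.325, adjusted p = 0.000709). Dpep3, a dipeptidase gene of the testis, had 0.0604 CPM in WT and 18.3 CPM in KO (ratio 300, 95% interval 82.7 to 2480, adjusted p = 0.00293). Iapp, which encodes the islet peptide amylin, had no count in WT and was at least 79-fold higher (adjusted p = 0.0139). Iapp lies within the span of Slco1a5, which also rose, and counts without strand cannot show that the genes rose apart. Trdc, a constant region of the T cell receptor, rose from 2.41 to 38.8 CPM (log2 change 4.01, adjusted p = 0.0133). Gabrr1, a GABA receptor subunit gene, had a ratio of 74.8 (20.3 to 623, adjusted p = 0.0139). Cntn2, an adhesion molecule of myelinated fibres, fell by 1.37 on the log2 scale, from 272 ± 13.7 to 105 ± 3.70 CPM (SD, n = 2 each, SE 0.156, adjusted p = 0.0328).

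Of 15672 genes tested in astrocytes, 15 rose and 1 fell, and 1200 had an unadjusted p under 0.05. DESeq2 called 74 higher and 134 lower, which include these 16. The count depended on single pools of animals. It was 424 (108 higher, 316 lower) without WT replicate 1, 136 (43 higher, 93 lower) without WT replicate 2, 31 (all higher) without KO replicate 2 and 12 (all higher) without KO replicate 1. Mnd1 (log2 change 3.67, adjusted p = 0.0328), Slco1a5 (3.32, adjusted p = 0.0316) and Vmn2r78 (ratio 138, 24.3 to 5480, adjusted p = 0.025) were lost without KO replicate 1 (adjusted p = 0.0789, 0.148 and 0.064). Cntn2 was lost without either KO replicate (adjusted p up to 0.56).

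Marker lists of other cell types moved with the label in the astrocyte fraction. All 22 oligodendrocyte and myelin genes had a negative log2 change (median −1.07, camera adjusted p = 7.96e-55, and adjusted p = 0.117 with an estimated correlation). Of them 0 passed over all genes and 21 were lower when adjusted over the list alone. Mag, the myelin-associated glycoprotein gene, was at 794 ± 87.5 CPM in WT and 350 ± 32.0 CPM in KO (SD, n = 2 each, log2 change −1.19, adjusted p = 0.0715). The homeostatic microglia list was called higher (median 0.81, adjusted p = 3.26e-18, and adjusted p = 0.321 with an estimated correlation), with 0 of 22 past the threshold and 12 adjusted over the list alone. So was that of disease-associated microglia (median 0.46, adjusted p = 1.99e-12, and adjusted p = 0.295 with an estimated correlation), with 0 of 28 past the threshold and 10 adjusted over the list alone. P2ry13 of microglia had a log2 change of 1.29 (adjusted p = 0.116) and Gpnmb of 1.92 (adjusted p = 0.0653), while Hapln2 of oligodendrocytes had −1.19 (adjusted p = 0.0643). The astrocyte markers were called higher as well, with a median of 0.12 (0 of 29 past the threshold, 1 adjusted over the list alone, adjusted p = 0.00102, and adjusted p = 0.321 with an estimated correlation).

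Beside these markers, immune and reactive lists were called higher in the astrocyte fraction labelled KO, though no member of them passed on its own over all genes. Of 57 interferon-stimulated genes, 55 had a positive log2 change (median 0.65, adjusted p = 5.34e-24, and adjusted p = 0.295 with an estimated correlation), and 21 were higher when adjusted over the list alone. Oasl2 had 1.16 (adjusted p = 0.0877), Irf7, the gene of a regulator of type I interferon, 0.82 (adjusted p = 0.146) and the chemokine gene Cxcl10 2.67 (adjusted p = 0.158). The pan-reactive astrocyte list was called (median 0.22, adjusted p = 1.65e-05, and adjusted p = 0.295 with an estimated correlation), with 3 of 13 members adjusted over the list alone. Its member Gfap, the intermediate filament gene of astrocytes (chromosome 11, 102887336 to 102900912), was at 262 ± 60.8 CPM in WT and 804 ± 92.0 CPM in KO (SD, n = 2 each). Its log2 change of 1.62 (SE 0.208) did not pass the test (adjusted p = 0.0527). Complement was called (median 0.58, adjusted p = 9.62e-07, and adjusted p = 0.295 with an estimated correlation), with 4 of 21 members adjusted over the list alone. C4b had 1.03 (adjusted p = 0.187) and C3ar1 1.27 (adjusted p = 0.178). Cytokines and chemokines were called (median 0.31, adjusted p = 1.2e-09, and adjusted p = 0.321 with an estimated correlation), with 9 of 29 members adjusted over the list alone. MHC class II was called too (median 1.03, adjusted p = 9.65e-08, and adjusted p = 0.36 with an estimated correlation), with 1 of 8 members adjusted over the list alone. Some members are also in the microglia lists, such as Itgam of complement and Ccl3 of the cytokines and chemokines. Whether the immune lists rose within astrocytes or with a larger share of microglia in the fraction was not tested.

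The germline genes were called higher in astrocytes (median 0.70, adjusted p = 1.61e-08, and adjusted p = 0.317 with an estimated correlation), with 1 of 11 past the threshold and 4 adjusted over the list alone. Mitochondrially encoded genes were called higher too (median 0.44, adjusted p = 1.17e-06, and adjusted p = 0.378 with an estimated correlation), with 0 of 13 past the threshold and 3 adjusted over the list alone, and lost the call without WT replicate 1 (0.0522). The dissociation and immediate early response genes had 9 members higher and 5 lower of 28 adjusted over the list alone (adjusted p = 0.00285, and adjusted p = 0.409 with an estimated correlation). They lost the call without WT replicate 2 or KO replicate 2 (up to 0.261). MHC class I and antigen processing (median 0.31, adjusted p = 0.000158), the neuropeptides and neurotrophins (median 0.59, adjusted p = 0.000346) and the A1-type reactive astrocyte genes (median 0.34, adjusted p = 0.00338) were also higher. With an estimated correlation they had adjusted p = 0.36, 0.324 and 0.321. Cytosolic nucleic acid sensing (adjusted p = 0.0102), inhibitory neuron markers (adjusted p = 0.0244) and perivascular macrophages and leukocytes (adjusted p = 0.0357) were called higher and cholesterol synthesis lower (median −0.19, adjusted p = 0.0222). Their adjusted p with an estimated correlation was 0.321, 0.425, 0.329 and 0.321. These calls were lost without WT replicate 1 for sensing (0.212) and WT replicate 2 for the inhibitory neurons (0.507). The macrophages were lost without WT replicate 1 or KO replicate 1 (up to 0.154) and cholesterol synthesis without WT replicate 2 or KO replicate 1 (up to 0.126). In all, 17 lists were called higher and 2 lower, 0 with an estimated correlation, and fry called only the oligodendrocyte list (adjusted p = 0.00214). The clustered protocadherins were not called in astrocytes (median −0.28 over 40 members, 0 past the threshold, adjusted p = 0.299).

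Of 917 repeat subfamilies tested in the astrocyte fraction labelled KO, 11 rose and 0 fell. MuLV-int, the internal part of murine leukaemia virus-related elements, rose from 9.02 ± 0.564 to 3186 ± 530 CPM (SD, n = 2 each, log2 change 8.46, SE 0.246, adjusted p = 1.13e-06). MMERVK10C-int rose by 3.53 on the log2 scale (from 13.2 to 153 CPM, adjusted p = 9.38e-05), IAP1-MM_I-int by 3.42 (adjusted p = 0.000417) and RLTR10C by 3.28 (adjusted p = 0.000113). The others rose by 1.87 to 2.78, among them MMERGLN-int (adjusted p = 0.00806), RLTR44-int and IAP1-MM_LTR (adjusted p = 0.012 each). IAPEY3-int, RLTR10B2, RLTR12A and RLTR44B lost the call without KO replicate 1 (adjusted p = 0.235, 0.275, 0.0592 and 0.118), which left 7 subfamilies. With only copies that overlap no gene, MuLV-int had 1.30 and lost the call (adjusted p = 0.634), while the other 10 kept it.

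A single MuLV-int copy on chromosome 8 (123426327 to 123434006, within the spans of Gm20388 and Def8), singled out after its values were seen, held 99.75% of the KO counts of its subfamily. It had 86 and 17 counts in the WT libraries and 57169 and 43034 counts in the KO libraries (log2 change 10.02, adjusted p = 0.00489). Of 3926 copies tested in astrocytes, 166 rose and 0 fell. This direction depended on the WT libraries, since 391 copies were higher and 404 lower without WT replicate 1, and 229 higher and 77 lower without WT replicate 2. Without KO replicate 2, 93 were higher and 0 lower, and without KO replicate 1, 76 and 0. Outside genes 145 of 1499 rose, and such copies tested alone gave 159 higher and 5 lower. Over all tested copies of MMERVK10C-int, within and outside genes, 31 of 37 rose (83.78%). The subfamily holds 3230 copies, and a copy silent in WT is tested only if its KO counts are high enough. This share therefore does not stand for the whole subfamily. Among the highest were an L1M2 (chromosome 17, 67839436 to 67839940), an L1M5 (67840583 to 67840893) and an ORR1D1 (67838955 to 67839287) near Arhgap28. Another was an MMERGLN-int copy on chromosome 7 (28221167 to 28223706), 2652 bp from Gm45011.

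**Figure D3:**
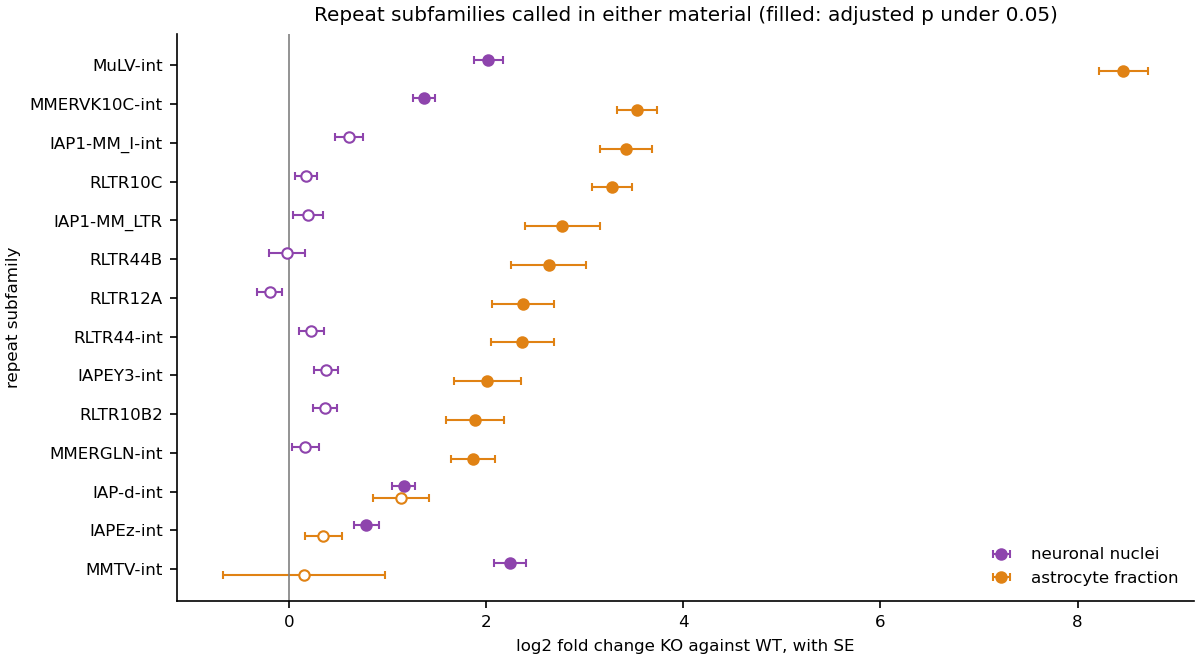
Log2 fold change of KO against WT with its SE for the 14 repeat subfamilies called in nuclei or astrocytes, with filled points past the threshold of the material. MuLV-int stands at 8.46 in the astrocyte fraction and at 2.02 in nuclei, and all the subfamilies called in either material are higher in KO there.

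In cortex tissue labelled KO, 21 of 55 clustered protocadherins and 9 of 22 germline genes rose, as did the complement gene C4b and the astrocyte gene Gfap. A smaller set of genes fell, among them Klf10, Cckbr and the protocadherin Pcdha9. Gfap rose from 111 ± 14.4 to 311 ± 66.1 CPM (SD, n = 3 each, log2 change 1.48, SE 0.119, adjusted p = 0.00026). C4b rose from 16.2 ± 3.01 to 78.3 ± 23.8 CPM (SD, n = 3 each, log2 change 2.27, SE 0.241, adjusted p = 0.00152), and it shares sequence with its copy C4a, so its level is uncertain. Atf7ip, which encodes the nuclear partner of SETDB1, rose from 91.7 ± 5.16 to 198 CPM (log2 change 1.11, SE 0.078, adjusted p = 0.000104). Mkrn3, an imprinted gene expressed from the paternal copy, rose from 0.507 to 12.9 CPM (log2 change 4.65, adjusted p = 6.83e-06). Klf10, a zinc finger transcription factor gene, fell by 1.02 on the log2 scale (from 54.3 ± 7.67 to 26.8 ± 3.35 CPM, SE 0.097, adjusted p = 0.000809). Cckbr, a cholecystokinin receptor gene, fell by 0.61 (from 74.6 to 48.7 CPM, adjusted p = 0.00457). Within batch 1 the log2 changes were 1.45 for Gfap, 2.06 for C4b, 1.08 for Atf7ip, 4.64 for Mkrn3, −1.04 for Klf10 and −0.65 for Cckbr, with adjusted p of at most 0.00942.

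Of 16700 genes tested in cortex, 188 rose and 46 fell in KO against WT, and 2385 had an unadjusted p under 0.05. The change was at least 2-fold in 154 and 11. Within batch 1 alone, 356 were higher and 231 lower, and these include 193 of the 234. Leaving out a library moved the counts to 100 higher and 17 lower (WT replicate 1), 80 and 7 (WT replicate 2), 98 and 20 (WT replicate 3), 105 and 10 (KO replicate 1) and 519 and 360 (KO replicate 3). Klk1b24 (at least 46.6-fold higher, adjusted p = 0.00325) and Dpep3 (at least 23.5-fold, adjusted p = 0.00598) had no count in WT cortex. The same held for Mael (at least 102-fold, adjusted p = 0.0329), Zfp981 (at least 31.3-fold, adjusted p = 0.0232), Tnxa (at least 19.7-fold, adjusted p = 0.0127) and Iapp (at least 19.1-fold, adjusted p = 0.013). Mael and Zfp981 were lost without any 1 of the WT libraries or KO replicate 1 (up to 0.125 and 0.0942). Tnxa was lost without WT replicate 2 or 3 (up to 0.0605) and Iapp without WT replicate 2, WT replicate 3 or KO replicate 1 (up to 0.0737). Bglap3, of the osteocalcin family, had a log2 change of 7.49 (from 0.123 to 23.6 ± 17.5 CPM, SD, n = 3, adjusted p = 0.00471), and 7.32 within batch 1.

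The other lowest genes of cortex KO were Pcdha9 (log2 change −1.46, SE 0.246, adjusted p = 0.0195), Sstr2, a somatostatin receptor gene (−1.38, from 33.9 ± 7.76 to 13.9 ± 7.33 CPM, SD, n = 3 each, adjusted p = 0.0362), Trim17 (−1.33, adjusted p = 0.0128) and Casp2 (−1.24, adjusted p = 0.0212). They also included Ccn4 (−1.21, adjusted p = 0.0143), Fam43a (−1.14, adjusted p = 0.0299) and Tnnt2 (−1.11, adjusted p = 0.015). Within batch 1 the log2 changes were −1.20 for Pcdha9, −1.04 for Sstr2, −1.48 for Trim17, −1.46 for Casp2, −1.36 for Ccn4, −1.21 for Fam43a and −1.11 for Tnnt2. Each lost the call without KO replicate 1 and without WT replicate 2. Calls were also lost without WT replicate 1 (Sstr2, Trim17, Casp2, Ccn4), WT replicate 3 (Pcdha9, Sstr2, Trim17, Fam43a, Tnnt2) or KO replicate 2 (Casp2, Fam43a, Tnnt2). Over these fits the adjusted p reached 0.0949 for Pcdha9, 0.169 for Sstr2, 0.0719 for Trim17, 0.109 for Casp2, 0.0847 for Ccn4, 0.165 for Fam43a and 0.0987 for Tnnt2.

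The clustered protocadherins moved both ways in cortex KO. Of 55 tested, 21 rose and 1 fell (30 and 6 adjusted over the list alone), and 39 had a positive and 16 a negative log2 change. The median was 0.58 (adjusted p = 3.48e-49, and adjusted p = 0.0322 with an estimated correlation) and 0.63 within batch 1. Pcdha1 rose from 1.76 ± 0.43 to 38.8 ± 3.96 CPM (SD, n = 3 each, log2 change 4.46, SE 0.168, adjusted p = 3.54e-06), Pcdha8 by 4.48 (adjusted p = 1.25e-05) and Pcdhb17 by 1.58 (adjusted p = 5.62e-05), while Pcdha9 fell. The rises were 4.63, 4.21 and 1.53 in batch 1 alone. Of 22 germline genes, 9 rose and 0 fell (17 and 0 adjusted over the list alone). Their median was 1.92, unchanged with the genes at 0 set to their bound (adjusted p = 3.91e-26, and adjusted p = 0.0322 with an estimated correlation), and 2.03 within batch 1. Stag3 rose by 4.05 (from 0.218 to 3.74 CPM, adjusted p = 0.000203, within batch 1 3.95). Ddx4, a helicase gene of germ cells, rose by 2.92 (adjusted p = 0.012, within batch 1 2.87) and was lost without WT replicate 2, WT replicate 3 or KO replicate 1 (up to 0.0847). Of the 36 lists 11 were called higher and 5 lower, and only the protocadherins and the germline genes kept the call with an estimated correlation.

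Glial and immune lists were called higher in cortex KO. The pan-reactive astrocyte list had a median of 0.56 (adjusted p = 0.000653, and adjusted p = 0.124 with an estimated correlation) and 0.43 within batch 1 (adjusted p = 0.014). Of its 10 members 2 rose and 0 fell (3 and 1 adjusted over the list alone), namely Gfap and Aspg (log2 change 1.57, adjusted p = 0.0238, within batch 1 1.23), and Osmr had 0.94 (adjusted p = 0.0938). The interferon-stimulated genes had a median of 0.53 (adjusted p = 6.53e-07, and adjusted p = 0.503 with an estimated correlation). Of 50 members 2 rose and 0 fell (9 and 0 adjusted over the list alone), namely Lgals3bp (log2 change 1.11, adjusted p = 0.0019, within batch 1 1.01) and Oasl2 (1.82, adjusted p = 0.0237, within batch 1 1.59). Aspg was lost without any 1 of the WT libraries or KO replicate 1, and Oasl2 without any 1 of the WT libraries or KO replicate 2 (both up to 0.136). The interferon list was not called within batch 1 (median 0.35, adjusted p = 0.0606) or without KO replicate 3 (0.134).

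Complement as a list had a median of 0.33 in cortex KO (1 of 22 higher, adjusted p = 0.00871, and adjusted p = 0.503 with an estimated correlation). Disease-associated microglia genes had a median of 0.23 (0 of 24 past the threshold, adjusted p = 0.00523, and adjusted p = 0.503 with an estimated correlation). Both were lost within batch 1 (adjusted p = 0.224 and 0.137) and without KO replicate 3 (0.378 and 0.385). The homeostatic microglia list had a median of 0.14 (adjusted p = 0.0314, and adjusted p = 0.62 with an estimated correlation). It was lost within batch 1 (0.553) and without WT replicate 3, KO replicate 2 or KO replicate 3 (up to 0.523). The astrocyte markers had a median of 0.14 (1 of 29 higher, adjusted p = 0.00254, and adjusted p = 0.503 with an estimated correlation) and were called within batch 1 (adjusted p = 0.00326). MHC class II (median 0.80, adjusted p = 0.0143), the A1-type reactive astrocyte genes (median 0.60, adjusted p = 0.0235) and the imprinted genes (median 0.12, adjusted p = 0.0109) were called too, each with an adjusted p = 0.503 with an estimated correlation. MHC class II was lost without WT replicate 1 or KO replicate 2 (up to 0.224) and the imprinted genes without KO replicate 2 (0.0724). The A1-type list was lost within batch 1 (0.239) and without WT replicate 1, KO replicate 2 or KO replicate 3 (up to 0.501).

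The oligodendrocyte and myelin genes were called lower in cortex KO, and all 22 had a negative log2 change (median −0.56, adjusted p = 6.3e-06, and adjusted p = 0.58 with an estimated correlation), with 0 past the threshold over all genes. In batch 1 alone the median was −1.13 (adjusted p = 1.48e-17). Without KO replicate 2 the list was lost (adjusted p = 0.0588), and its median ranged from −1.23 to −0.13 over the libraries left out. The genes of ependyma, choroid plexus and red blood cells were called lower (median −0.53, adjusted p = 0.00576, and adjusted p = 0.503 with an estimated correlation), with −0.87 within batch 1. All 16 endothelial markers were negative too (median −0.26, 0 past the threshold, adjusted p = 0.000624, and adjusted p = 0.503 with an estimated correlation), also within batch 1 (median −0.25, adjusted p = 0.00317). The excitatory neuron markers had a median of −0.18 (adjusted p = 0.00309, and adjusted p = 0.13 with an estimated correlation) and −0.13 within batch 1 (adjusted p = 0.00187). Of 20 members 1 fell (3 adjusted over the list alone), namely Neurod6, a transcription factor gene of cortical excitatory neurons. It fell by 0.82 (from 81.6 to 45.3 CPM, SE 0.125, adjusted p = 0.0127, within batch 1 −0.99) and was lost without WT replicate 1, WT replicate 2 or KO replicate 1 (up to 0.0694). Tbr1 had −0.41 (adjusted p = 0.093).

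The immediate early response genes were called lower in cortex KO (median −0.28, adjusted p = 0.000473, and adjusted p = 0.503 with an estimated correlation), with 1 of 28 higher and 3 lower. Egr1, a transcription factor gene induced by neuronal activity, fell by 0.74 (from 307 to 188 CPM, adjusted p = 0.0235). Its log2 change was −0.63 within batch 1 (adjusted p = 0.0652), and it was lost without WT replicate 2, WT replicate 3 or KO replicate 1 (up to 0.138). The list was not called within batch 1 (median −0.03, adjusted p = 0.389) or without KO replicate 3 (0.37).

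DKO cortex had few calls against KO, and likeness was not tested. Against KO, edgeR called 0 genes higher and 1 lower of 16700, 619 had an unadjusted p under 0.05, and DESeq2 called 20 higher and 16 lower. Within batch 1 alone 1 gene was higher and 2 lower. A difference of opposite sign in the 2 batches is weakened in the joint fit. Against KO, Gfap had −0.38 and C4b −0.62 (adjusted p = 1 each).

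Camera called 9 of the 36 lists in DKO against KO, 4 lower and 5 higher, and 0 with an estimated correlation. The clustered protocadherins were lower (median −0.15, 0 past the threshold, adjusted p = 7.59e-06, and adjusted p = 0.473 with an estimated correlation), also within batch 1 (−0.19, adjusted p = 1.86e-05). So were the germline genes (median −0.47, 0 past the threshold, adjusted p = 0.00017, and adjusted p = 0.473 with an estimated correlation), with −0.61 within batch 1 (adjusted p = 0.00198), and their call was lost without DKO replicate 1 (0.0642). The immediate early response genes were higher (median 0.44, 2 adjusted over the list alone, adjusted p = 4.83e-13, and adjusted p = 0.447 with an estimated correlation), with 0.27 within batch 1 (adjusted p = 0.00362). Their member Egr3 was at 154 CPM in KO and 251 CPM in DKO (log2 change 0.72, adjusted p = 0.824). The genes of ependyma, choroid plexus and red blood cells were higher (median 0.43, 3 adjusted over the list alone, adjusted p = 2.96e-07, and adjusted p = 0.447 with an estimated correlation), with 0.55 within batch 1 (adjusted p = 8.1e-05). The choroid plexus gene Ttr had 1.42 (adjusted p = 0.32). The interferon-stimulated genes were called lower over both batches (median −0.19, adjusted p = 9e-05, and adjusted p = 0.806 with an estimated correlation). Within batch 1 their median was 0.06 (adjusted p = 0.573), and the call was lost without KO replicate 3 or DKO replicate 3 (up to 0.814). The other 4 lists had medians between −0.09 and 0.15. They were homeostatic microglia (lower, adjusted p = 0.00351), cholesterol synthesis (higher, adjusted p = 0.00464), A2-type reactive astrocytes (higher, adjusted p = 0.0238) and neuropeptides and neurotrophins (higher, adjusted p = 0.0464). Their adjusted p with an estimated correlation was 0.732, 0.683, 0.683 and 0.473, and it was 0.573, 0.573, 0.132 and 0.0297 in batch 1 alone. Each was lost without KO replicate 3. The microglia were also lost without KO replicate 2, DKO replicate 2 or DKO replicate 3 (up to 0.619) and cholesterol synthesis without DKO replicate 3 (up to 0.792). The A2-type list was lost without KO replicate 1, DKO replicate 1 or DKO replicate 3 (up to 0.232) and the neuropeptides without KO replicate 2, DKO replicate 1 or DKO replicate 2 (up to 0.452).

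Against WT, 123 genes rose and 21 fell in cortex labelled DKO, and 1693 had an unadjusted p under 0.05. The change was at least 2-fold in 100 and 8. Tcfl5 rose from 0.572 to 33.8 CPM (log2 change 5.88, adjusted p = 5.24e-06) and Pcdha1 to 31.5 ± 3.43 CPM (SD, n = 3, log2 change 4.16, adjusted p = 3.6e-06). Mkrn3 rose by 4.56 (adjusted p = 8.35e-06), Stag3 by 3.82 (adjusted p = 0.000387) and Atf7ip by 0.95 (adjusted p = 0.000365). Gfap rose to 239 ± 43.3 CPM (SD, n = 3, log2 change 1.10, adjusted p = 0.0022). Within batch 1 the log2 changes were 5.59 for Tcfl5, 4.28 for Pcdha1, 4.37 for Mkrn3, 3.81 for Stag3, 0.93 for Atf7ip and 1.05 for Gfap. C4b was at 51.2 ± 8.16 CPM (SD, n = 3, log2 change 1.65, adjusted p = 0.0117), had 1.38 within batch 1 (adjusted p = 0.0592) and was lost without any 1 of the WT libraries (up to 0.0747). Trim17 fell by 1.77 (adjusted p = 0.00399, within batch 1 −1.76) and Klf10 by 0.77 (adjusted p = 0.00468, within batch 1 −0.69). Olfr482 had −3.27 (adjusted p = 0.0209), but −2.90 within batch 1 (adjusted p = 0.0578), and passed only without DKO replicate 2 (otherwise up to 0.0925). Neurod6 had −0.35 (adjusted p = 0.373), Cckbr −0.14 (adjusted p = 0.594) and Oasl2 1.16 (adjusted p = 0.221). The counts of changed genes were 59 higher and 5 lower without WT replicate 1, 57 and 5 without WT replicate 2, 66 and 7 without WT replicate 3 and 81 and 8 without DKO replicate 1. They were 72 and 7 without DKO replicate 2, 90 and 11 without DKO replicate 3 and 85 and 15 within batch 1.

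Lists called in DKO against WT were 6 higher and 3 lower, 0 with an estimated correlation. The protocadherins had 17 of 55 higher and 1 lower (28 and 6 adjusted over the list alone), with a median of 0.45 (adjusted p = 5.4e-41, and adjusted p = 0.0533 with an estimated correlation) and 0.38 within batch 1. The germline genes had 3 of 22 higher (14 adjusted over the list alone), with a median of 1.41 (adjusted p = 8.19e-21, and adjusted p = 0.0638 with an estimated correlation) and 1.41 within batch 1. The pan-reactive astrocyte list was called with 1 of 10 higher (median 0.52, adjusted p = 0.00194, and adjusted p = 0.142 with an estimated correlation, within batch 1 0.44). All 22 oligodendrocyte genes were negative (median −0.44, adjusted p = 0.000273, and adjusted p = 0.825 with an estimated correlation). Their median within batch 1 was −0.31 (adjusted p = 0.00193), and the call was lost without DKO replicate 3 (0.348). The interferon-stimulated genes (median 0.27), astrocyte markers (median 0.11) and imprinted genes (median 0.06) were called higher and the endothelial markers (median −0.13) lower, with an adjusted p of 0.00872 each. Excitatory neuron markers were lower too (median −0.15, adjusted p = 0.0204). With an estimated correlation these 5 lists had adjusted p of 0.911, 0.825, 0.825, 0.825 and 0.254. The imprinted and endothelial calls were lost within batch 1 (adjusted p = 0.173 and 0.316). Leaving out 1 library ended the interferon call (WT replicate 3, DKO replicate 1 or DKO replicate 2, up to 0.144) and that of the astrocyte markers (WT replicate 1, WT replicate 2 or DKO replicate 2, up to 0.316). It also ended the calls of the imprinted genes (DKO replicate 3, 0.348), the endothelial markers (WT replicate 3 or DKO replicate 3, up to 0.403) and the excitatory neurons (WT replicate 1 or DKO replicate 1, up to 0.0603).

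All 234 genes changed in KO against WT had the same sign in DKO against WT, and 130 passed in both. These genes were selected for their change in KO, so their sizes in KO and DKO are not compared, and both comparisons use the same WT libraries. Over all genes their log2 changes had a correlation of 0.865, against 0.496 (highest 0.524) in 20 simulations of unchanged groups with shared controls. The covariance was 0.284, against 0.0438 (highest 0.0483). Genes higher in both numbered 114, against 0.05 in the simulations and 1.38 for independent lists, and genes lower in both 16, against 0 and 0.0578. A split of the 3 WT libraries would leave fewer than 2 to 1 of the comparisons and was not made. The simulations hold no real effects, so part of the excess of shared genes may still come from the shared controls.

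**Figure D4:**
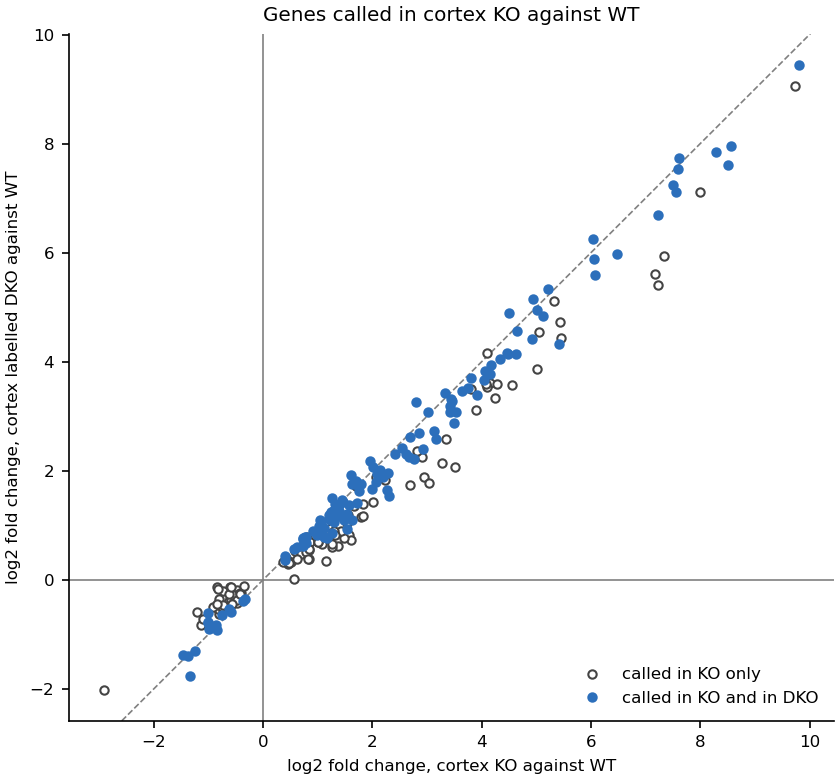
Log2 fold change of DKO against WT plotted against that of KO against WT for the 234 genes called in cortex KO against WT, with filled points called in both and the dashed line at equal change. All 234 points have the same sign on both axes, and values for the 11 genes at 0 in WT are fitted. The genes were selected for their change in KO, so distances from the dashed line are not a comparison of KO with DKO.

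The genes changed in the 3 materials overlapped. Of 15372 genes tested in nuclei and cortex, 97 were higher in both, out of 233 in nuclei and 157 in cortex (2.38 by chance, one-sided Fisher's exact test p = 2.38e-143). Among them were Stag3, Mael, Tnxa, Klk1b24, Zfp981, Mkrn3, Atf7ip, C4b and Pcdha1. Lower in both were Tnnt2, Tmem132d, Coch and Vegfa (0.138 by chance, Fisher's exact test p = 1.04e-05). Between astrocytes and cortex, 9 of the 15 higher genes were shared (0.117 by chance, Fisher's exact test p = 3.72e-16), namely Tcfl5, Mnd1, Slco1a5, Iapp, Apoc1, Dpep3, Trdc, Gm13283 and Gm48619. Of these, Iapp lies within the span of Slco1a5, so they may not be separate changes. Nuclei and astrocytes shared Tcfl5, Mnd1 and Gmnn (0.0656 by chance, Fisher's exact test p = 2.5e-05) and 0 lower genes. Tcfl5 and Mnd1 were called in all 3 materials.

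The KO effect was tested for a difference between nuclei and astrocytes over 24220 genes. It differed in 64 genes, with the more positive log2 change in nuclei for 46 and in astrocytes for 18, and 1778 had an unadjusted p under 0.05. P2rx7 and C4b were among the former. C4b was at 3.21 ± 1.79 CPM in WT nuclei and 173 ± 25.1 CPM in the nuclei labelled KO (SD, n = 3 each), and the difference of its effect was 4.68 on the log2 scale (adjusted p = 4.16e-05). Without astrocyte KO replicate 2 the balance turned, with 20 genes more positive in nuclei and 30 in astrocytes. In the same order the numbers were 279 and 46 without astrocyte WT replicate 1, and 10 and 7 without astrocyte KO replicate 1. They were 19 and 12 without nuclei WT replicate 2, 20 and 12 without nuclei KO replicate 1 and 23 and 13 without nuclei KO replicate 2. The materials differ in platform, age, sex and nuclear against cellular RNA, which the fit takes up in the levels but not in the effect.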

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

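The tests of repeat subfamilies between nuclei and astrocytes, of neuronal RNA and of a larger share of other cells in the astrocyte fraction, of mislabelled nuclei and of exons outside the deleted part were chosen only after the result was seen. Groups of 2 or 3 libraries were too small for a test of single outlying libraries.

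The results below stand out because the KO effect differed between nuclei and the astrocyte fraction by the interaction test. Among them P2ry13 and Ighm are in the microglia and leukocyte lists, and Cntn2 is a gene of myelinated fibres. Their differences may follow the share of other cells in the astrocyte fraction, which was not tested. Each value is the log2 change in nuclei minus that in astrocytes, with its adjusted p. It was 4.68 for C4b (4.16e-05, 5.73 in nuclei and 1.03 in astrocytes), 4.02 for P2rx7 (3.98e-07, 3.89 and −0.16) and 3.58 for Stag3 (1.75e-05, 3.87 and 0.26), which passed in all 10 fits that left out 1 library. It was −4.96 for Trdc (0.00019, −0.93 and 4.01), also in all 10 fits, −5.97 for Gabrr1 (0.00718, 0.14 and 6.05) and 1.47 for Cntn2 (0.00471, 0.13 and −1.37), and the last of these and Gabrr1 were lost without astrocyte KO replicate 1 (adjusted p = 0.0585 and 0.0672). It was −2.73 for Tnfaip2 (0.0209, −2.37 and 0.35), −2.07 for Ighm (0.0363, −0.68 and 1.37), −1.68 for P2ry13 (0.0439, −0.37 and 1.29) and −1.77 for Reln (0.0497, −0.70 and 1.05), which passed in 4, 3, 3 and 2 of the 10 fits.

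Repeat subfamilies were compared in the same way, and each of those below had the larger log2 change in astrocytes. The difference was −6.47 for MuLV-int (2.69e-10, 2.02 in nuclei and 8.46 in astrocytes), −3.13 for RLTR10C (1.32e-07, 0.18 and 3.27), −2.84 for IAP1-MM_I-int (2.05e-05, 0.61 and 3.42), −2.69 for RLTR44B (0.00105, −0.02 and 2.63), −2.61 for IAP1-MM_LTR (0.000365, 0.20 and 2.77) and −2.60 for RLTR12A (4.16e-05, −0.19 and 2.38). It was −2.19 for MMERVK10C-int (1.99e-05, 1.37 and 3.53), −2.17 for RLTR44-int (0.000272, 0.23 and 2.37), −1.74 for MMERGLN-int (0.00105, 0.17 and 1.87), −1.67 for IAPEY3-int (0.00343, 0.37 and 2.01) and −1.55 for RLTR10B2 (0.00337, 0.36 and 1.88). For MMERVK10C-int this order holds on the log2 scale alone, since it went from 312 to 806 CPM in nuclei and from 13.2 to 153 CPM in astrocytes. MuLV-int gained more in CPM in astrocytes too (from 9.02 to 3186) than in nuclei (from 23.04 to 93.6). In nuclei 90.77 to 92.03% of the repeat counts lay within gene spans, where reads of introns add to a repeat. With only copies that overlap no gene, MMERVK10C-int had log2 changes of 1.89 in nuclei and 3.82 in astrocytes and MuLV-int 0.74 and 1.30, and the difference was not tested on these copies.

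The targeted genes were not lower in every group that carries a mutant label. Swapped or mislabelled nuclei libraries are argued against, since 93, 95.5 and 93.6% of the 157 genes called higher in cortex KO lay above the WT mean in the nuclei libraries KO 1, 2 and 3, against 52.8, 47.3 and 56.8% of other genes. Counts from exons outside the deleted part cannot be told apart from an intact gene, because the whole-gene count, with a log2 change of 0.223 for P2rx7 in DKO against KO, does not separate exons. Cells in which the deletion did not take place also stay open, untested.

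The 15 genes higher in the astrocyte fraction labelled KO were weighed against neuronal RNA carried over from KO cells. The gains in CPM would need a median of 9740% of the gain in nuclei, with over 100% for 14 of the 15 genes, the lowest need at 89.8% for Mnd1 and no gain in nuclei for 4, while the genes most raised in nuclei appeared at a median of 8.44%, so this source is excluded as the whole cause, with the limit that nuclear and cellular RNA were compared. P2rx7, at 82.7 CPM in the nuclei labelled KO, was at 20.3 CPM in this fraction. A larger share of another cell type is argued against as the whole cause only for types that 1 of the 10 marker lists follows as a whole. The highest list, homeostatic microglia, had a median of 0.81 and an upper quartile of 0.91, below the lowest log2 change of the 15 genes, 2.30 for Gmnn (SE 0.273). The 15 genes were called for large changes, which weakens this test. The leukocyte list pools several cell types and cannot bound a rise of 1 of them, and Trdc is a T cell receptor gene. A changed state of the cells in this fraction, or cells without a marker list of their own here, stays open and untested.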

How the results depend on the processing

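No alternative in this part was chosen after a result was seen. Of the single genes, lists, subfamilies and copies named, 5214 values under an alternative kept direction and side of the threshold, 685 kept direction and lost the call, 193 gained it and 53 reversed. RLE factors gave 345, 16, 234, 1 and 144 genes in nuclei, astrocytes, cortex KO, DKO against KO and DKO against WT, of which 345, 16, 234, 1 and 143 are among the reported ones, and 63 for the interaction, with 61 shared. The cause of the moves below was not tested, except that fewer libraries were read where one was left out or batch 1 was used alone. Depth limits genes with few counts, and in astrocytes 32.8% of simulated 2-fold changes were recovered.

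With no filter the counts of genes were 677 in nuclei, 1444 in cortex KO, 118 in DKO against KO, 947 in DKO against WT and 443 for the interaction, among them all 345, 234, 1, 144 and 64 reported ones. DESeq2 called 208 genes in astrocytes, 522 in cortex KO, 36 in DKO against KO, 271 in DKO against WT, 212 for the interaction and 8 subfamilies in nuclei. A log2 limit of 1 left 225 genes in nuclei. Batch 1 alone gave 587 genes in cortex KO and 3 in DKO against KO. Only the 6 libraries compared gave 3 genes in DKO against KO and 292 in DKO against WT. Copies outside genes gave 21 subfamilies in nuclei, sharing 3 with the 5 reported (MMTV-int and MuLV-int were lost), and 15 in astrocytes, sharing 10 with the 11 reported (MuLV-int was lost). Lists called with an estimated correlation were 2 in nuclei, 0 in astrocytes, 2 in cortex KO, 0 in DKO against KO and 0 in DKO against WT, and with fry 3, 1, 4, 0 and 3 in the same order.

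The replicate numbers were not taken to pair the samples, and the values here do not settle whether they do. Same-numbered libraries had correlations of their deviations of 0.145, 0.098 and 0.305 in nuclei, 0.161, −0.058 and 0.197 for cortex KO and WT, 0.032, 0.232 and 0.169 for DKO and WT, 0.077, −0.294 and −0.127 for KO and DKO, and 0.159 for astrocytes, and not every library correlated best with its own number (nuclei WT 1 with KO 2, 0.175). Nuclei libraries with different numbers had correlations of −0.29 to 0.175. As all same-numbered nuclei libraries had positive values, a pairing in nuclei stays open. The astrocyte value is bound by the 2 libraries per genotype and cannot tell. With the number as a block the counts were 511 genes, 11 lists and 10 subfamilies in nuclei, 238 genes in astrocytes, 193 in cortex KO, 2 in DKO against KO, 110 in DKO against WT and 128 for the interaction.

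With 1 library left out, where a lone astrocyte library is assumed to vary like the other group, the counts ranged as follows. Genes were 220 (without KO 1) to 489 (without WT 3) in nuclei, 12 (KO 1) to 424 (WT 1) in astrocytes, 87 (WT 2) to 879 (KO 3) in cortex KO, 62 (WT 2) to 101 (DKO 3) in DKO against WT and 17 (astrocyte KO 1) to 325 (astrocyte WT 1) for the interaction. Lists were 7 (KO 3) to 12 (WT 2) in nuclei and 6 (KO 3) to 17 (KO 1) in DKO against KO. In astrocytes, subfamilies were 7 (KO 1) to 12 (WT 1) and copies 76 (KO 1) to 795 (WT 1).

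Of the 53 reversals, 43 came with a library left out, 8 with batch 1 alone, 1 with only 6 libraries and 1 with DESeq2. In DKO against KO, batch 1 alone gave log2 changes of −0.10 for Setdb1, −0.14 for H2-DMb1, 0.038 for Gpnmb, −0.075 for Tmem212, −0.02 for Fam208a and 0.059 for the interferon list, and Sstr2 had 0.03 with only 6 libraries and 0.009 with DESeq2. In DKO against WT, batch 1 alone gave 0.28 for Ciita and −0.19 for Hbb-bs. With a library left out, ranges in DKO against KO were −0.089 to 0.238 for Setdb1, −0.12 to 0.49 for P2rx7, −1.35 to 0.24 for Mael, −0.84 to 0.69 for Bglap3, −0.17 to 0.22 for Pcdha9, −0.35 to 0.23 for Sstr2, −0.19 to 0.085 for Casp2, −0.34 to 0.022 for Serping1, −0.23 to 0.19 for H2-DMb1, −0.20 to 0.065 for Sparc, −0.39 to 0.13 for Gpnmb, −0.30 to 0.082 for Fkbp5, −0.31 to 0.081 for Ggta1, −0.22 to 0.046 for Aqp4 and −0.072 to 0.343 for Sox10. They were −0.052 to 0.547 for Enpp2, −0.27 to 0.45 for Trf, −0.58 to 0.79 for Tmem212, −0.021 to 0.061 for Fam208a, −0.27 to 0.058 for Mkrn3, −1.19 to 0.19 for Dlk1, −0.44 to 0.088 for Htr3a and −0.38 to 0.068 for the interferon list. In DKO against WT they were −0.58 to 0.26 for Ciita, −0.14 to 0.003 for Cldn5 and −0.21 to 0.30 for Hbb-bs. Each of these but the interferon list was not past the threshold with all libraries in the comparison given.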

Other observations

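No test in this part was chosen after its result was seen, and only the libraries that the high splits separate were looked up afterwards.

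Receptor genes and chromatin genes of the cortex labelled KO moved within lists that were not called as a whole. Of 39 monoamine and neuropeptide receptor genes, 1 rose and 2 fell (adjusted p of the list 0.444). Htr3a, a serotonin receptor subunit gene, rose from 6.99 to 17.6 CPM (log2 change 1.34, adjusted p = 0.0195, within batch 1 1.36, lost without any WT library or KO replicate 1, up to 0.11), while Cckbr and Sstr2 fell. Of 28 genes of SETDB1 partners and H3K9 methylation, 2 rose and 1, Setdb1, fell (adjusted p of the list 0.152). Beside Atf7ip the other that rose was Fam208a, a gene of the HUSH silencing complex (log2 change 0.41, adjusted p = 0.0476, within batch 1 0.41, kept only without KO replicate 3, otherwise up to 0.205). In DKO against WT, Htr3a had a log2 change of 1.27 (adjusted p = 0.0354, within batch 1 0.91, lost without any WT library or DKO replicate 2, up to 0.213).

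A part of the genes outside the protocadherin clusters that rose in the nuclei labelled KO lay close to repeat copies that rose too. Of 243 such genes, 87 (35.8%) had at least 1 of the 2026 higher copies outside genes within 50 kb, against a mean of 2.03% and a highest value of 7% in 10000 draws of tested genes matched on mean expression (permutation p = 1e-04, the smallest that these draws can give). Genes were drawn singly and not matched on position or on the density of repeats. Raised neighbours, such as Prr23a2 and Prr23a3, can share a copy, so the draws can overstate the contrast. Raised repeat copies and genes may therefore share a local change, a hypothesis that these counts cannot separate from transcripts that run from a gene into a copy or the reverse. A preferred position of the copies upstream of the genes was not found: 25 genes had a copy upstream only, 31 downstream only and 31 on both sides (exact binomial test of upstream against downstream, two-sided p = 0.504).

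Each count of a comparison of 3 against 3 libraries was set beside the other splits of the same 6 libraries. There are 10 splits, too few for a share under 0.05. In nuclei the real split called 345 genes and the highest other split 0, so 1 of 10 splits gave as many. For copies the real split called 3332 and the highest other 4 (1 of 10), for lists 6 and 16 (8 of 10) and for subfamilies 5 and 647 (2 of 10). The split with 647 subfamilies sets WT 1, WT 2 and KO 2 against the rest and follows the share of counts that repeats take in a library, which points to a structure of the samples. For cortex KO against WT the values were 234 and 0 genes (1 of 10) and 16 and 17 lists (2 of 10), for DKO against WT 144 and 0 genes (1 of 10) and 9 and 10 lists (4 of 10), and for DKO against KO 1 and 91 genes (3 of 10) and 9 and 15 lists (5 of 10). The split with 91 genes sets KO 1, KO 2 and DKO 3 against the rest. It keeps the labels KO and DKO in batch 1 and swaps them in batch 2. Its genes therefore tended to differ between KO and DKO in opposite directions in the 2 batches. The batches also differ in Xist, and whether batch, sex or single libraries lie behind this was not tested. Within batch 1 the real split called 3 genes.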
